A study of Rattus norvegicus with 12 samples.

How the data were processed

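Gene expression was measured on 12 Affymetrix rat expression arrays, 1 for each donor animal. The deposited values are log2 signals per probe set, which the authors made with RMA (background correction, quantile normalization between arrays and a summary over the probes of each set) and, per the submitters' processing notes, used with limma. The versions and settings of both are not given in the sources used here. The arrays share nearly 1 distribution, with median log2 signals from 5.83 to 5.90, so each value is relative to the rest of the same array, and a loss of RNA that touched every transcript alike would leave no trace. Intensities have no count depth: the number of arrays limits the precision, together with a floor near log2 3.00 and a ceiling near log2 14.50.

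The value table held 31099 probe sets, of which 57 were controls. Among the other 31042, 20826 carried 1 gene symbol, 436 carried several and 9780 carried none in the platform table. For 20758 of the probe sets with 1 gene, the gene ID matched a reference annotation of the rat (assembly GRCr8), which was used for names alone. Each of 14217 genes was represented by the probe set with the highest mean over all 12 arrays, and 4525 of these genes had more than 1 probe set. Control probe sets stayed out of all gene tests and served to describe RNA quality.

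Samples were grouped by their labels into heart-beating donors and donors dead for 4, 16 or 30 h, with 3 animals in each group. A model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, which left 8 residual degrees of freedom and gave 4.89 prior degrees of freedom. The comparisons were each time after death against heart-beating donors, and each pair of times. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. Calls with a log2 difference of at least 1 in size were counted as changed at least 2-fold, and a moderated F test over the 3 comparisons with heart-beating donors summarised the whole design. No filter on dim probe sets and no further normalization was applied.

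The comparisons, the lists, the rule for naming genes and all settings but 2 were chosen before the data were examined. The rule named the 10 largest rises and 10 largest falls in each comparison with heart-beating donors, and the 5 largest of each between times, among called genes whose 3 arrays in 1 group all lay above the 3 of the other. It added up to 4 members of a described list, those with the smallest p, and Alb, Fos, Hmox1, Cps1 and Cyp2e1 in every comparison. Gapdh and Actb appear through their control probe sets. Where fewer genes passed than the rule asked for, all that passed were named.

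The 45 lists, 10 of them markers of cell types, held 1215 entries, of which 1042 were measured. Each was tested in each of the 6 comparisons with camera at a preset correlation between genes of 0.01, adjusted over all 270 tests, with camera at an estimated correlation and fry beside it. Camera compares a list with the other genes, and fry tests whether its members move 1 way on balance. For each list, members were also counted as called over all genes and as called when adjusted over the list alone. RNA quality was described by the log2 difference between the 3' and the 5' control probe sets of a transcript, with an exact two-sided permutation test. With 3 arrays against 3, such a test cannot give a p below 0.1.

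The gene test was tested on simulated data in which 100 genes were moved by a log2 difference of 0.5 and 100 by 1. At 4 h it called 75 and 98 of them with 6 false calls, at 16 h 74 and 96 with 5, and at 30 h 70 and 95 with 6. Each gene was drawn independently of the others, with the same spread in every group. These counts therefore do not cover correlation between genes or the larger spread of the 30 h arrays. In the test of lists on simulated data without any change, but with the correlation between genes kept, camera at the preset correlation gave p under 0.05 in 303 of 900 tests (33.7%). With an estimated correlation it did so in 27 of 900 (3%).

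The alternatives were median centring, cyclic loess and a further quantile normalization, the upper 50% of genes by mean signal, the mean of all probe sets of a gene, all probe sets one by one, a variance trend with robust settings, array weights, a fit of only the groups compared, the animal's number as a replicate block, and leaving out each array. After the data were seen, the Gapdh 3' to 5' difference as a covariate and a fit without the 30 h arrays were added. Probe sets with several gene symbols or none were left out of the gene tests, because they could not be tied to 1 gene, and were tested apart.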

Results

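Hepatocytes were isolated from rat livers by collagenase perfusion and used for RNA without a period in culture. Donors were heart-beating animals or animals that had been dead for 4, 16 or 30 h, 3 animals per group, so every value below has n = 3 per group unless another number is given. The labels give the strain as Fischer 334. The question of the design was how the transcripts of hepatocytes taken from a liver after death differ from those of a heart-beating donor, and how this depends on the interval. Replicate arrays correlated at 0.9932 to 0.9968 among heart-beating donors, 0.9952 to 0.9957 at 4 h, 0.9954 to 0.9969 at 16 h and 0.9913 to 0.9939 at 30 h. The median standard deviation between replicates was 0.08 log2 units in heart-beating donors, 0.09 at 4 h, 0.09 at 16 h and 0.12 at 30 h. The first principal component held 41% of the variance and placed the 30 h arrays (16.79 to 29.71) apart from the heart-beating arrays (-13.69 to -10.29) and the 4 h arrays (-12.86 to -12.55), with the 16 h arrays (-1.80 to 4.88) between them. The second, with 21.7%, set the 16 h arrays at its low end (-22.90 to -12.46).

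RNA quality differed with time after death. The Gapdh control probe set at the 3' end exceeded that at the 5' end by a log2 difference of 0.39 ± 0.08 (SD) in heart-beating donors and 0.38 ± 0.10 at 4 h, against 1.05 ± 0.20 at 16 h and 1.97 ± 0.29 at 30 h. The exact two-sided permutation p against heart-beating donors was 1.0 at 4 h and 0.1 at both later times, the smallest value that 3 arrays against 3 can give. For Actb, the difference was 1.85 ± 0.05 in heart-beating donors, 1.71 ± 0.15 at 4 h (exact p = 0.2), 2.21 ± 0.33 at 16 h (exact p = 0.2) and 2.87 ± 0.11 at 30 h (exact p = 0.1). The 3' signal of Gapdh, a glycolytic enzyme, was 11.84 ± 0.02 in heart-beating donors and 11.79 ± 0.11 at 30 h (exact p = 0.8), while its 5' signal was 11.45 ± 0.09 and 9.82 ± 0.39 (exact p = 0.1). The 3' signal of Actb, a cytoskeletal actin, differed from that of heart-beating donors by -0.53 at 16 h and -0.45 at 30 h (exact p = 0.1 for each). The difference between the 2 brightest probe sets of the same gene could be followed in 1510 genes: it changed in 3 of them (0.199%) at 4 h, 358 (23.7%) at 16 h and 822 (54.4%) at 30 h against heart-beating donors.

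**Figure D1:**
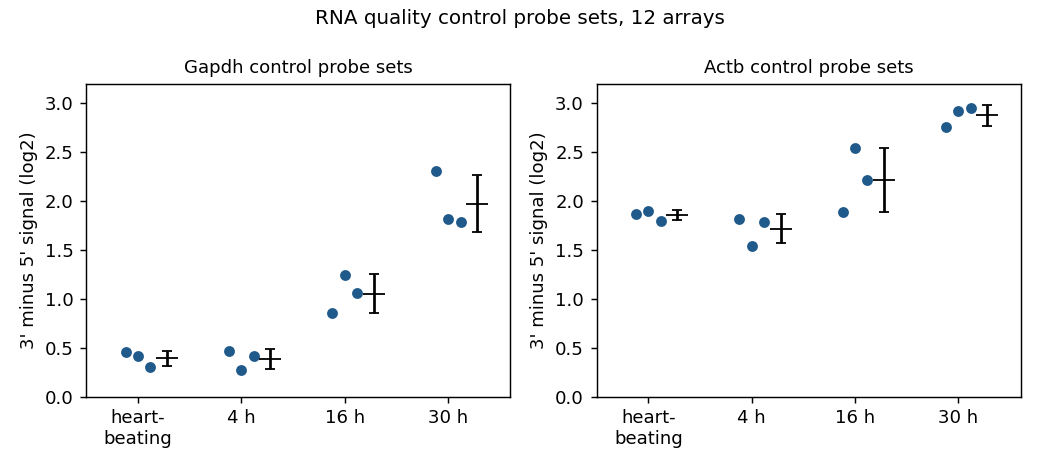
Log2 difference between the 3' and the 5' control probe sets of Gapdh (left) and Actb (right) on each of the 12 arrays, by donor group; points are arrays, and the bars beside them are the mean and SD. For Gapdh, the 30 h arrays lie between 1.79 and 2.31, above the heart-beating arrays at 0.31 to 0.45.

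**Figure D2:**
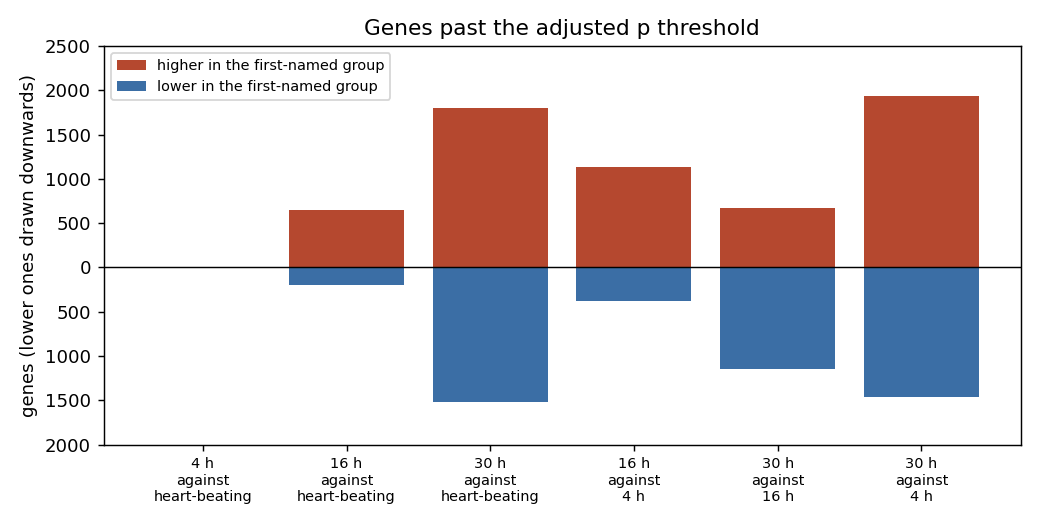
Number of genes past an adjusted p of 0.05 in each of the 6 comparisons, with genes higher in the first-named group drawn upwards and lower ones downwards. At 4 h against heart-beating donors the count was 1, and at 30 h it was 3318.

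Hepatocytes isolated 4 h after death were compared with those of heart-beating donors to find early changes. Scd2, a desaturase that makes monounsaturated fatty acids, rose 8.46-fold, from a log2 signal of 7.60 ± 1.02 to 10.69 ± 0.44 (SD), with a log2 difference of 3.08 (SE 0.39, adjusted p = 0.0435). It was the only gene of 14217 called by limma, with 785 genes at an unadjusted p under 0.05 where 711 would be expected by chance. Fos, an immediate early transcription factor, differed by 2.14 (SE 0.57, adjusted p = 0.648), and 0 of 37 measured immediate early genes passed (2 higher when adjusted over the list alone). The control spread was wide in some of these genes, with an SD of 1.97 for Jun and 1.75 for Atf3 among heart-beating donors, where donor 2 was the highest (Jun 10.44 against 6.70 and 7.52). The other genes named in every comparison lay close to the control level: Alb (albumin) differed by 0.00, Cps1 (the entry enzyme of the urea cycle) by -0.02, Cyp2e1 (a drug-metabolizing cytochrome P450) by 0.04 and Hmox1 (a stress-inducible heme oxygenase) by 0.06, with SE from 0.05 to 0.09. Alb was measured at the top of the scale, where a change would be hard to see.

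The genes next in order at 4 h, chosen after their values were seen and not past the threshold (adjusted p = 0.184 for each), were Apoa1 (-0.52, SE 0.08), an apolipoprotein of high-density lipoprotein, Zfp36 (0.84, SE 0.14), an RNA-binding protein that destabilizes cytokine transcripts, the chemokines Cxcl14 (0.68, SE 0.12) and Ccl5 (0.46, SE 0.08), and Tsx (-0.78, SE 0.14). Markers of Kupffer cells, the resident macrophages of the liver, had a median log2 difference of 0.10 with 17 of 19 above 0, and proteasome subunits one of -0.13 with 31 of 33 below 0, but 0 members of either list passed, over all genes or adjusted over the list alone. With the preset correlation 12 of 45 lists were called at 4 h, 6 higher and 6 lower, these 2 among them (adjusted p = 0.000138 and 8.21e-06). With an estimated correlation 0 were called (adjusted p = 0.918 with an estimated correlation for both), and fry called 0. The erythroid list was among those called higher at the preset correlation (adjusted p = 0.00369; adjusted p = 0.918 with an estimated correlation), with 9 of 10 genes above 0 and 0 passing, over all genes or adjusted over the list alone. Without 4 h animal 1 the Kupffer and erythroid lists were no longer called at the preset correlation, and without 4 h animal 3 the proteasome list was not. The call of Scd2 ended with a variance trend and robust settings, with only the groups compared, with a replicate block, and without heart-beating donor 1 (log2 difference 3.02), donor 3 (2.61), 4 h animal 2 (2.99), 4 h animal 3 (2.92), any 1 of the 16 h animals, or 30 h animal 1 or 2 (3.08 for each of these).

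Hepatocytes isolated 16 h after death were compared with those of heart-beating donors in the same way. Clock genes carried the largest changes. Dbp, a clock output transcription factor, rose 13.3-fold (log2 difference 3.73, SE 0.19, adjusted p = 2.27e-07), and the clock repressors Nr1d2 and Nr1d1 rose by 3.00 (SE 0.33) and 2.93 (SE 0.14). Npas2, an activator of the clock, fell by 1.71 on the log2 scale (SE 0.13, adjusted p = 3.2e-05). Of 17 measured clock genes, 6 rose, 4 fell and 7 did not pass (8 higher and 5 lower when adjusted over the list alone), with Tef (1.11, SE 0.12) and Per3 (1.50, SE 0.17) among the rises and Bmal1 (-1.15, SE 0.13) and Cry1 (-1.02, SE 0.23) among the falls. Per3, Bmal1 and Cry1 stand outside the rule for named genes and were chosen after their values were seen. The list was called by fry (adjusted p = 0.0386) and not by camera (adjusted p = 0.191 at the preset correlation, adjusted p = 0.918 with an estimated correlation).

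**Figure D3:**
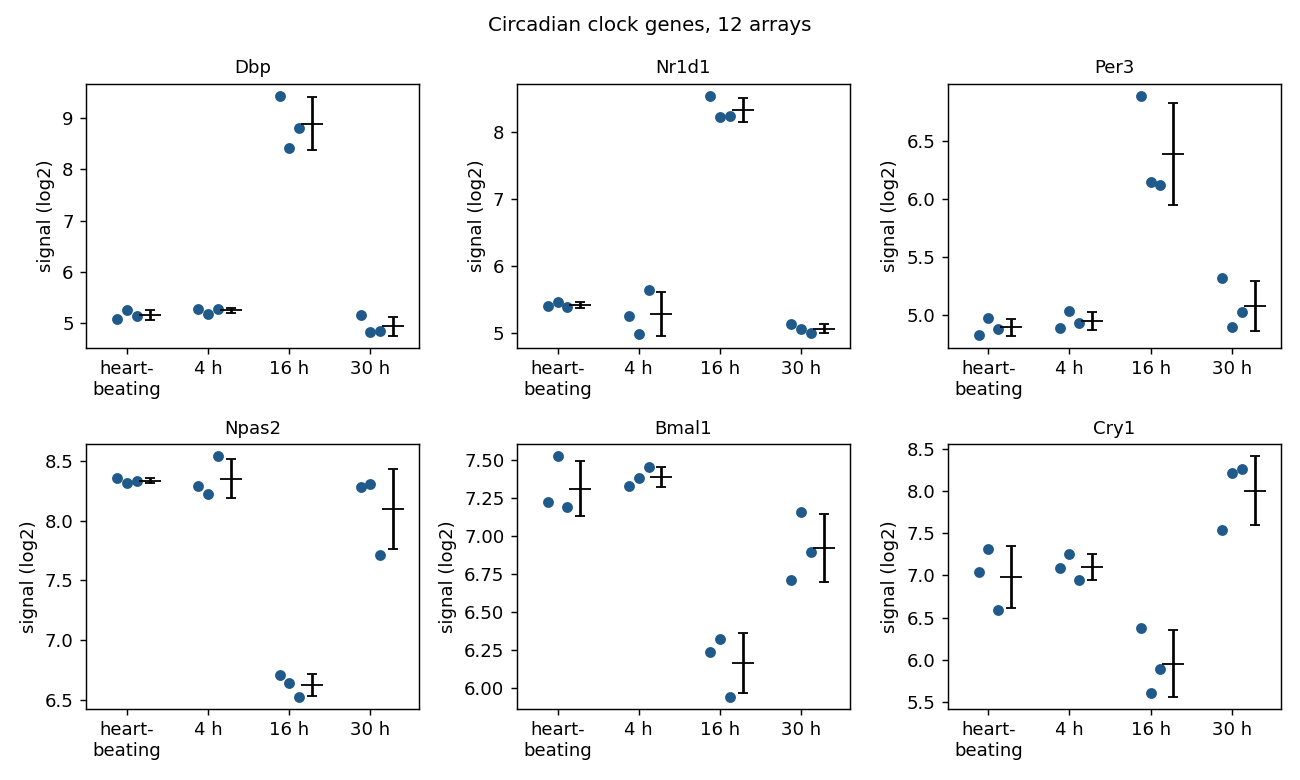
Log2 signal of 6 clock genes on each of the 12 arrays, by donor group, each panel with its own axis; points are arrays, and the bars beside them are the mean and SD. The 3 arrays of the 16 h group lie above all others for Dbp, Nr1d1 and Per3 and below all others for Npas2, Bmal1 and Cry1.

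Other large rises at 16 h were Hsd17b2 (2.83, SE 0.13), which oxidizes sex steroids, Cpt1a (1.85, SE 0.21), which admits fatty acids to mitochondrial oxidation, Proser2 (1.79, SE 0.36) and Gadd45b (1.64, SE 0.31), a stress-induced growth arrest gene. The red cell transcripts Alas2 (2.45, SE 0.53), Hbb (1.85, SE 0.32) and Hba-a3 (1.59, SE 0.31), for heme synthesis and globin, rose as well. At the preset correlation the erythroid list was not called at 16 h. It stayed uncalled in 15 of 21 settings and was called in the rest. The largest falls, beside Npas2, were Mug1 (-1.86, SE 0.31), a protease inhibitor of rodent plasma, Tubb2a (-1.71, SE 0.24), a tubulin, Scd2 (-1.68, SE 0.39), the chemokine Ccl6 (-1.59, SE 0.20), Lgalsl (-1.56, SE 0.10), Chka (-1.45, SE 0.21), a choline kinase, Dipk2a (-1.29, SE 0.19), Tmem37 (-1.23, SE 0.24) and Rprm (-1.19, SE 0.25). Adjusted p for the 10 largest rises and 10 largest falls, clock genes included, lay between 1.19e-07 and 0.0261. Other probe sets were called the same way for Nr1d2 (1 of 2) and Lgalsl (1 of 1). Of those of Cpt1a (1), Proser2 (1), Dipk2a (2) and Scd2 (3), 0 were called. Alb (0.00), Cps1 (0.01), Cyp2e1 (0.01), Hmox1 (-0.03) and Fos (0.64) were not called at 16 h.

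Markers of macrophages fell at 16 h: 7 of 19 passed, all lower, and 12 did not (7 lower and 1 higher when adjusted over the list alone), led by Cd5l (-0.91, SE 0.12), Cd14 (-0.65, SE 0.10) and Adgre1 (-0.88, SE 0.15), all proteins of Kupffer cells. Markers of liver endothelial cells moved the other way, with 5 of 19 higher and 0 lower (the same counts when adjusted over the list alone), among them Lyve1 (0.88, SE 0.13) and Fcgr2b (0.78, SE 0.14). These lists were called at the preset correlation (adjusted p = 1.99e-06 and 0.00288) but not otherwise (adjusted p = 0.918 with an estimated correlation for both, fry adjusted p = 0.0567 and 0.142). In gluconeogenesis 3 of 11 measured genes rose and 0 fell (4 and 0 when adjusted over the list alone), with Creb3l3, a fasting-responsive transcription factor, at 0.51 (SE 0.07). That list was called at the preset correlation (adjusted p = 0.00409; adjusted p = 0.918 with an estimated correlation) and by fry (adjusted p = 0.0272), but not among the upper 50% of genes by mean signal. Of 48 nuclear subunits of oxidative phosphorylation 5 fell and 0 rose, with Uqcrc2 of complex III at -0.84 (SE 0.12) and Ndufb8 of complex I at -0.61 (SE 0.10). The count was 5 when adjusted over the list alone, and the list was called at the preset correlation (adjusted p = 3.16e-06) but not otherwise (adjusted p = 0.918 with an estimated correlation). The Gapdh 3' to 5' difference of these arrays exceeded that of heart-beating donors by 0.66 log2 units.

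In total limma called 845 genes at 16 h, 651 higher and 194 lower, and 47 changed at least 2-fold, 34 higher and 13 lower. The share of higher genes was 77%, and it was 62.3% after cyclic loess and 60.2% after a further quantile normalization. The count depended on single animals: it was 549, 551 and 261 without heart-beating donor 1, 2 and 3, 299 and 244 without 16 h animal 1 and 2, and 1328 without 30 h animal 1. Changes of at least 2-fold numbered 74 without heart-beating donor 2, 31 without donor 3 and 30 without 16 h animal 2. Without any 30 h array, a setting added after the data were seen, 1526 genes were called. With the Gapdh difference as a covariate the count was 102, of which 57 were among the 845 called before. The median change of the 845 genes went from 0.46 to 0.48, with 98.6% in the same direction, and the median SE from 0.10 to 0.17. Among the genes named, Alas2 was no longer called with a variance trend or without heart-beating donor 1 (2.37), donor 3 (2.56) or 16 h animal 2 (2.27). Proser2 was not called without donor 3 (1.69), 16 h animal 1 (1.70) or 2 (1.80). Gadd45b was not called without the same donor (1.48) or animals (1.53 and 1.58). Hba-a3 lost its call without 16 h animal 2 (1.56). Tmem37 lost it without 16 h animal 1 (-1.13) or 2 (-1.17). Rprm lost it without heart-beating donor 2 (-1.07), donor 3 (-1.20) or 16 h animal 1 (-1.01). Scd2 lost it with the mean of its probe sets (-0.53), with a variance trend, and without heart-beating donor 1 (-1.75), donor 2 (-1.14), 16 h animal 1 (-1.57) or 2 (-1.68).

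Hepatocytes isolated 30 h after death were compared with those of heart-beating donors as the longest interval. Mug1 changed most and fell 19.1-fold (log2 difference -4.26, SE 0.31, adjusted p = 1.1e-05), to a signal of 4.99 ± 0.16 (SD) at 30 h. Falls followed in Cd36 (-2.78, SE 0.24), a fatty acid transporter, Ccl6 (-2.20, SE 0.20), Msra (-2.16, SE 0.15), which repairs oxidized methionine, Tmem14c (-2.11, SE 0.24), Micos13 (-1.996, SE 0.18), of the mitochondrial inner membrane, and Serpina7 (-1.73, SE 0.51), a thyroid hormone carrier. Atp5pb (-2.08, SE 0.18), Atp5mg (-1.82, SE 0.18) and Uqcrc2 (-1.89, SE 0.12), subunits of ATP synthase and complex III, completed the 10 largest. The largest rises were Alas2 (2.45, SE 0.53), Hbb (1.89, SE 0.32) and Hba-a3 (1.80, SE 0.31), then Ppp1r3b (1.33, SE 0.25), a glycogen-targeting phosphatase subunit, Ybx3 (1.23, SE 0.22), Mga (1.22, SE 0.16), Itga6 (1.19, SE 0.15), an integrin, Pik3c2a (1.19, SE 0.09), Cpne3 (1.17, SE 0.13) and Abcc3 (1.16, SE 0.20), an exporter of bile acids and conjugates. Adjusted p for these 20 genes lay between 5.54e-06 and 0.0253. The 1 other probe set of Uqcrc2 was also called lower. Of the other probe sets of Mga (2), Itga6 (3) and Ppp1r3b (1), 0 were called, so each of these rises rests on 1 probe set.

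Many transcripts of mitochondrial energy metabolism were lower at 30 h. Of 48 nuclear subunits of oxidative phosphorylation 32 fell, 0 rose and 16 did not pass (37 lower when adjusted over the list alone), with a median log2 difference of -0.39; Ndufb8 (-1.53, SE 0.10) and Ndufa8 (-1.05, SE 0.10) of complex I were among them. In the tricarboxylic acid cycle 12 of 19 fell and 2 rose (the same counts when adjusted over the list alone), with Suclg1 (-1.34, SE 0.23) and Dld (-1.05, SE 0.17) lower and Aco1 (0.57, SE 0.07), the cytosolic aconitase that also binds iron-responsive RNA, higher. In fatty acid oxidation 11 of 23 fell and 2 rose (12 and 2 when adjusted over the list alone), with Hadh at -1.17 (SE 0.18) and Decr1 at -0.85 (SE 0.12). Of 22 antioxidant enzymes 12 fell and 2 rose (14 and 5 when adjusted over the list alone), with Gpx4 (-1.14, SE 0.15), which reduces lipid peroxides, and Gsr (-0.98, SE 0.09), which regenerates glutathione. These 4 lists were called at the preset correlation (adjusted p = 9.08e-15, 0.00288, 0.00288 and 0.000641) but not with an estimated one (adjusted p = 0.918 with an estimated correlation for each), and fry called the first and the last (adjusted p = 0.0272 for both). The fatty acid oxidation list also lost its call after a further quantile normalization. On the same arrays the Gapdh 3' to 5' difference exceeded that of heart-beating donors by 1.58 log2 units.

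Among transcripts of cytosolic ribosomal proteins 20 of 41 fell, 0 rose and 21 did not pass (22 lower and 1 higher when adjusted over the list alone), with Rpl7 at -1.18 (SE 0.16). Among those of proteasome subunits 16 of 33 fell, 2 rose and 15 did not pass (17 lower and 3 higher when adjusted over the list alone), with Psmd8 at -1.10 (SE 0.16). The adjusted p at the preset correlation was 1.39e-06 and 0.000679 (adjusted p = 0.918 with an estimated correlation for both), and a further quantile normalization ended the call of the ribosomal list. Of 38 apoptosis regulators listed, 32 were measured: 0 were called at 16 h and 1 at 30 h, the death receptor Fas (-1.18, SE 0.11), also 1 when adjusted over the list alone. Among 17 hepatocyte markers 5 fell and 1 rose (6 and 1 when adjusted over the list alone; the list was not called, adjusted p = 0.17). The asialoglycoprotein receptor subunits Asgr2 (-1.33, SE 0.16) and Asgr1 (-1.14, SE 0.17) fell, and Hnf4a, a master regulator of hepatocyte identity, rose by 0.76 (SE 0.11) by its brightest probe set, with -0.08 as the mean over its probe sets. Alb (0.00, SE 0.05) and Fos (0.65, SE 0.57) were not called. Neither was Cps1 at 0.08 (SE 0.06), but its other probe set read -1.70 (SE 0.19, adjusted p = 7.36e-05), and the other probe set of Pik3c2a likewise read -0.40 (SE 0.07, adjusted p = 0.00112). Hmox1 (-0.29, SE 0.09, adjusted p = 0.032) and Cyp2e1 (-0.24, SE 0.08, adjusted p = 0.0493) fell slightly.

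Among cell type markers, 10 of 19 of macrophages fell at 30 h and 0 rose (12 lower when adjusted over the list alone), with Adgre1 at -1.38 (SE 0.15), Cybb at -1.25 (SE 0.16), Cd5l at -1.18 (SE 0.12) and Cd68 at -0.87 (SE 0.13). Of 21 markers of stellate cells and fibroblasts 9 rose and 0 fell (13 higher when adjusted over the list alone), with Pdgfra at 0.67 (SE 0.10) and Colec11 at 0.44 (SE 0.08). At the preset correlation the adjusted p was 1.39e-06 and 0.00169 (adjusted p = 0.918 with an estimated correlation for both), and by fry 0.0272 and 0.079. Of 10 erythroid genes 4 rose and 0 fell (5 higher when adjusted over the list alone): Hbb, Alas2, Ahsp (0.66, SE 0.11), the chaperone of alpha globin, and Bpgm (0.94, SE 0.18), the enzyme of red cell bisphosphoglycerate. The list was called at the preset correlation (adjusted p = 0.0214; adjusted p = 0.918 with an estimated correlation) and by fry (adjusted p = 0.0456). Its call ended with the mean of all probe sets and without 30 h animal 1. On the arrays that carry these marker changes the Gapdh 3' to 5' difference was 1.97 at 30 h against 0.39 in heart-beating donors.

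**Figure D4:**
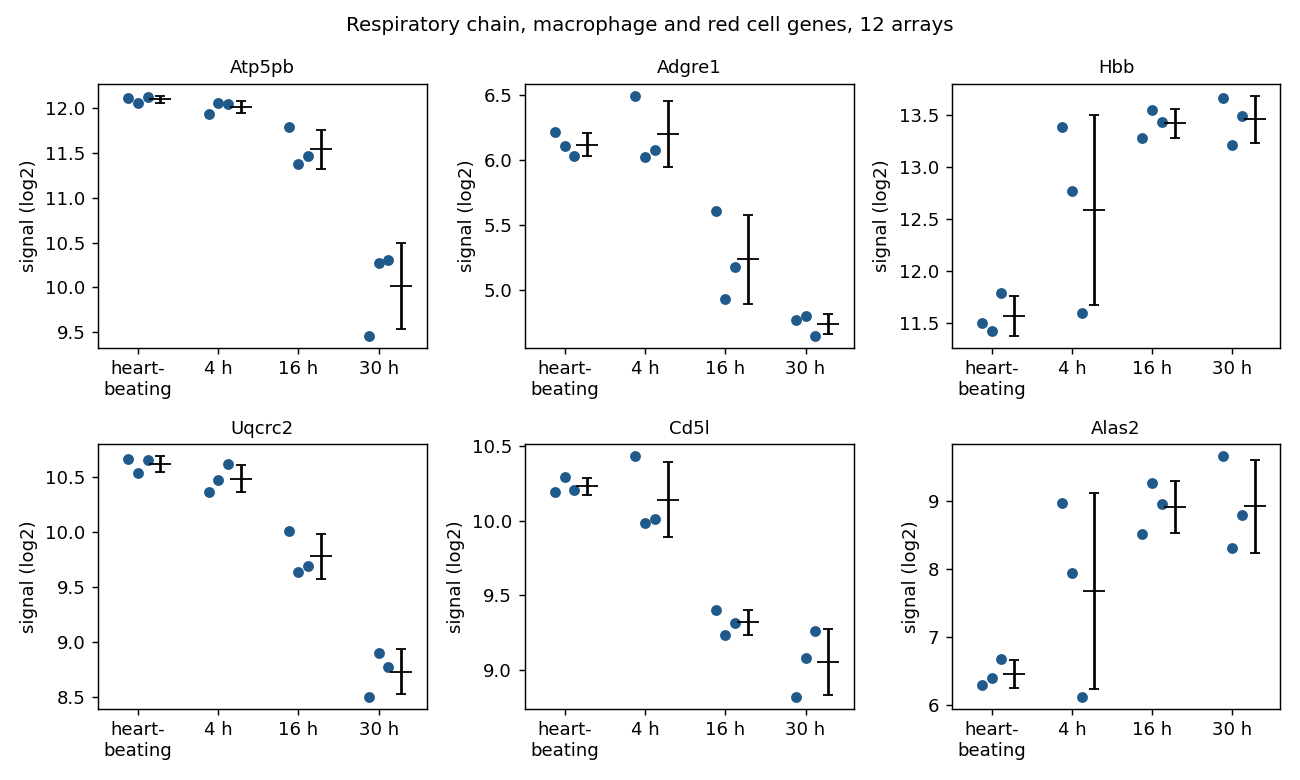
Log2 signal of respiratory chain, macrophage and red cell genes on each of the 12 arrays, by donor group, each panel with its own axis; points are arrays, and the bars beside them are the mean and SD. Uqcrc2 is lower on every 30 h array than on any other array (group mean 8.73 at 30 h and 10.61 in heart-beating donors), and Hbb averaged 11.57 in heart-beating donors and 13.45 at 30 h.

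In total limma called 3318 genes at 30 h, 1802 higher and 1516 lower, and 150 changed at least 2-fold, 22 higher and 128 lower. Which direction held more genes depended on the settings: after median centring 1534 were higher and 1809 lower, and with the mean of all probe sets 1393 and 1615. With the Gapdh 3' to 5' difference as a covariate, a setting added after the data were seen, 0 genes were called. The median change of the 3318 genes went from 0.43 (median SE 0.10) to 0.18 (median SE 0.33) in the original direction. Of these genes 62% kept their direction. The covariate separates the 30 h arrays from the heart-beating ones completely, which widens the error. Changes of at least 2-fold numbered 92 without 30 h animal 1. Ppp1r3b lost its call with the mean of its probe sets (0.54). Serpina7 lost it with a variance trend, with only the groups compared, and without heart-beating donor 1 (-1.13), donor 3 (-1.79), 30 h animal 2 (-1.80) or 3 (-1.50). Hmox1 lost it with array weights (-0.20), with only the groups compared, with a replicate block, and without heart-beating donor 1 (-0.26), 2 (-0.28) or 3 (-0.32) or 30 h animal 1 (-0.21) or 2 (-0.28). Cyp2e1 lost it after cyclic loess (-0.02) or a further quantile normalization (-0.16), with array weights (-0.17), with all probe sets one by one, with only the groups compared, with a replicate block, and without any 1 array except 30 h animals 2 and 3 (-0.28 to -0.15 without 1 heart-beating donor or 30 h animal 1, and -0.24 without any 1 of the 4 h or 16 h animals).

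The calls at 16 h and 30 h overlapped: 372 genes were higher and 136 lower at both times against heart-beating donors, where independent lists of these sizes would share 82.5 and 20.7, and 11 were called in opposite directions. Both comparisons use the same 3 control arrays. In 20 simulations of unchanged groups with shared controls 0 genes were called the same way at both times. The simulations drew each gene independently and held no true change, so almost no calls could arise. Their count of 0 cannot gauge how much overlap the shared controls give. The log2 differences correlated across genes at 0.505, against 0.496 in those simulations, and their covariance was 0.0335 against 0.0066. Genes are not independent replicates.

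The intervals were then compared with each other. From 4 h to 16 h the clock genes Dbp (3.64, SE 0.19), Nr1d2 (3.13, SE 0.33) and Nr1d1 (3.06, SE 0.14) rose, with Hsd17b2 (2.91, SE 0.13) and Cyp7a1 (2.27, SE 0.34), the rate-limiting enzyme of bile acid synthesis. Scd2 fell by 4.76 on the log2 scale (SE 0.39), and falls followed in Stac3 (-2.24, SE 0.54), Mug1 (-1.85, SE 0.31), Npas2 (-1.73, SE 0.13) and Lgalsl (-1.54, SE 0.10). Macrophage markers fell in 11 of 19 and rose in 0 (14 lower when adjusted over the list alone), with Cd14 at -0.91 (SE 0.10). In contrast, 6 of 22 genes of bile acid synthesis and transport rose and 0 fell (the same counts when adjusted over the list alone), with the canalicular exporter Abcc2 at 1.23 (SE 0.12). At the preset correlation the adjusted p was 5.95e-10 and 0.000969 (adjusted p = 0.918 with an estimated correlation for both), and by fry 0.0272 and 0.0278. Limma called 1511 genes, 1131 higher and 380 lower, and 70 changed at least 2-fold. The Gapdh 3' to 5' difference was 0.38 at 4 h and 1.05 at 16 h. The count was 806 and 693 without 16 h animal 1 and 2, and 875 and 956 without 4 h animal 1 and 2. With the Gapdh covariate it was 782, of which 362 were among the 1511 called before. The median change of the 1511 genes then went from 0.44 to 0.49 and the median SE from 0.10 to 0.17. The share of higher genes was 74.9%, and 59.4% after cyclic loess. Stac3 lost its call with a variance trend and without 4 h animal 2 (-2.10) or 3 (-1.58) or 16 h animal 2 (-2.07) or 3 (-2.11). Alb (0.00), Fos (-1.50), Hmox1 (-0.09), Cps1 (0.04) and Cyp2e1 (-0.03) were not called.

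From 16 h to 30 h the clock genes moved back. Dbp fell by 3.95 on the log2 scale (SE 0.19), Nr1d1 by 3.28 (SE 0.14) and Nr1d2 by 3.21 (SE 0.33), and Cry1 rose by 2.05 (SE 0.23) and Npas2 by 1.48 (SE 0.13). All 10 clock genes called at 16 h against heart-beating donors were called in the opposite direction between 16 h and 30 h. Hsd17b2 fell by 3.13 (SE 0.13) and Sds, a serine dehydratase that feeds gluconeogenesis, by 2.98 (SE 0.58), while Lgalsl rose by 2.19 (SE 0.10), G0s2, an inhibitor of lipolysis, by 1.91 (SE 0.43), Chka by 1.78 (SE 0.21) and the phosphate transporter Slc34a2 by 1.76 (SE 0.20). In gluconeogenesis 5 of 11 genes fell and 0 rose (6 lower when adjusted over the list alone), with Fbp1 at -0.94 (SE 0.17). Of 48 subunits of oxidative phosphorylation 19 fell and 0 rose (25 lower when adjusted over the list alone), with Atp5pb at -1.52 (SE 0.18). At the preset correlation the adjusted p was 0.00028 and 4.11e-10 (adjusted p = 0.918 with an estimated correlation for both), and by fry 0.0149 and 0.0803. Limma called 1821 genes, 676 higher and 1145 lower, and 115 changed at least 2-fold. The Gapdh 3' to 5' difference was 1.05 at 16 h and 1.97 at 30 h. Of the genes called in both steps, 293 moved in opposite directions, 222 of them up and then down, and 96 in the same direction. Both steps share the 16 h arrays, which favours opposite calls, and the excess was not tested. The count was 716 and 1161 without 16 h animal 1 and 2, and 7 with the Gapdh covariate. With that covariate the median change of the 1821 genes went from 0.45 to 0.20 and the median SE from 0.10 to 0.21. Of the 1821 genes, 75.7% kept their direction. The share of higher genes was 37.1%, and 48.7% after a further quantile normalization. Changes of at least 2-fold numbered 69 without 16 h animal 1 and 71 without 30 h animal 1, and G0s2 lost its call without 16 h animal 1 (1.62). Alb (0.00), Fos (0.01), Hmox1 (-0.26), Cps1 (0.07, with its other probe set at -1.26, SE 0.19, adjusted p = 0.00156) and Cyp2e1 (-0.25) were not called.

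From 4 h to 30 h the largest rises were Nrep (2.00, SE 0.28), Csad (1.49, SE 0.50), an enzyme of taurine synthesis, Mest (1.45, SE 0.27), Cyp7a1 (1.42, SE 0.34) and Pik3c2a (1.38, SE 0.09), whose other probe set read -0.38 (SE 0.07, adjusted p = 0.00166). Falls were largest in Mug1 (-4.25, SE 0.31), Scd2 (-3.78, SE 0.39), Serpina7 (-2.64, SE 0.51), the pancreatic protease Cpa1 (-2.54, SE 0.51) and Stac3 (-2.49, SE 0.54). Macrophage markers fell in 15 of 19 and rose in 0 (17 lower when adjusted over the list alone), with Adgre1 at -1.47 (SE 0.15). In contrast, 10 of 21 markers of stellate cells and fibroblasts rose and 0 fell (11 higher when adjusted over the list alone), with the collagens Col3a1 (1.36, SE 0.20) and Col1a2 (0.90, SE 0.17). Of 48 subunits of oxidative phosphorylation 28 fell and 0 rose (32 lower when adjusted over the list alone). These 3 lists were called at the preset correlation (adjusted p = 2.79e-10, 0.00827 and 1.42e-11), but not with an estimated one (adjusted p = 0.918 with an estimated correlation for each). By fry the adjusted p was 0.0138, 0.0885 and 0.0386, and the stellate list lost its call without 30 h animal 1. Limma called 3391 genes, 1932 higher and 1459 lower, and 146 changed at least 2-fold. The excess of rises did not hold after median centring (1704 higher, 1742 lower) or with the mean of all probe sets (1498 and 1542). The Gapdh 3' to 5' difference was 0.38 at 4 h and 1.97 at 30 h. With it as a covariate 0 genes were called (median change 0.44 before and 0.25 after, median SE 0.10 and 0.33). Of the 3391 genes, 66.8% kept their direction. Csad lost its call in most settings, including those without heart-beating donor 3 (1.49), any 1 of the 4 h animals (1.24 to 1.72), any 1 of the 16 h animals (1.49) or 30 h animal 2 (1.32) or 3 (1.42). Hmox1 fell by 0.35 (SE 0.09; not called with only the groups compared or without 4 h animal 1, -0.27) and Cyp2e1 by 0.28 (SE 0.08; not called after cyclic loess, -0.08, a further quantile normalization, -0.19, with only the groups compared, or without 4 h animal 2, -0.28, or 3, -0.27, or 30 h animal 1, -0.18). Alb (0.00), Fos (-1.49) and Cps1 (0.10, with its other probe set at -1.77, SE 0.19, adjusted p = 5.31e-05) were not called. Over the whole design the moderated F test called 3785 of 14217 genes as different between the 4 groups.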

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

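The tests of RNA loss, time of day and red cells below were chosen after the results had been seen, while the splits of the arrays were planned before. The times after death differed from each other and not only from heart-beating donors: 1511 genes differed between 16 h and 4 h, 1821 between 30 h and 16 h, and 3391 between 30 h and 4 h. Signals that belong to no gene test also differed between groups. The 5S ribosomal RNA probe set was higher than in heart-beating donors by a log2 difference of 1.63 at 4 h, 1.23 at 16 h and 2.31 at 30 h, and the hybridization controls were higher by 0.23 at 30 h (exact two-sided p = 0.1 for each, the smallest possible). Among 10216 probe sets without a single gene name, 314 changed at 16 h and 1408 at 30 h against heart-beating donors.

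Clock genes moved at 16 h and moved back at 30 h, but not all to the level of heart-beating donors. At 30 h, 3 of the 17 clock genes measured were called against heart-beating donors, and Cry1 averaged higher than in those donors. RNA loss that grows with time after death would not bring clock genes back. Yet all 10 of the clock genes called at 16 h moved back past the threshold at 30 h, which argues against such loss as the whole cause. A different time of day at death or collection in the 16 h group would put day and evening genes up and night and dawn genes down: 8 of 9 and 0 of 5 were higher (Fisher exact two-sided p = 0.003). This p treats genes of 1 feedback loop as independent and was computed after the directions were known, so it decides nothing. A clock that kept running after death may give the same picture, and with no time of day in the labels both explanations stay open.

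Among genes lower at 30 h, loss of RNA that differs along a transcript is a technical explanation. The difference between probe sets of the same gene changed in 54.4% of all genes with such a pair at 30 h. At 4 h it changed in 0.199%. This explanation predicts such an increase, but so does any cause that moves 2 probe sets of a gene unequally. At 4 h limma called only 1 gene, so a low share is likely there under any cause. The increase therefore cannot single out RNA loss. Among the 204 lower genes with a pair the difference changed in 158 (77.5%). These genes were called lower by the brightest probe set, which is also part of the pair. That choice by itself favours a changed difference, so this share is no support. Higher genes disagreed within themselves too: of 584 other probe sets with a mean above log2 6, 135 were called higher and 97 lower. Loss that differs along a transcript may account for part of the lower transcripts, those of mitochondria, ribosomes, proteasomes and macrophages alike. A loss of those transcripts in the living or dying cell was not tested apart from it, and neither were the rises at 30 h.

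Globin and Alas2 transcripts were higher at 16 h and 30 h, and also in 4 h animals 1 and 2 (Hbb 13.38 and 12.77, Alas2 8.96 and 7.94) but not in animal 3 (11.59 and 6.13), against at most 11.78 and 6.69 in heart-beating donors. If they rose only in relation to RNA lost in step with the Gapdh shift, the rise should have grown from 16 h to 30 h. The ratio expected was 2.39 (2.07 to 2.8 with 1 array left out). The mean rise of Hbb, Hba-a3 and Alas2 grew by 1.04 (0.926 to 1.15). Growth by 2.39 would take Hbb past the ceiling of the arrays and Hba-a3 close to it, so this mean cannot decide. Alas2 had room below the ceiling and rose by 2.45 at 16 h and at 30 h (SE 0.53 for each). For Alas2 alone this argues against loss in step with the Gapdh shift. In 4 h animals 1 and 2 the Gapdh 3' to 5' difference was 0.464 and 0.271, against 0.307 to 0.452 in heart-beating donors. Their higher globin and Alas2 signals thus came without such a shift, which argues against this explanation for these 2 animals. It does not decide the rises at 16 h and 30 h. Red cells carried over with the hepatocytes would tie Alas2 to Hbb within groups, and the exact two-sided permutation p for this was 0.00154. Both genes spread most at 4 h (SD 0.91 for Hbb and 1.43 for Alas2), so the tie rests mostly on that group. Any other cause that moves these transcripts together on an array would give the same tie, so this p cannot single out carry-over. Slc4a1, a red cell membrane gene, did not pass, so carry-over may be incomplete as an explanation. Its signal averaged 6.24 in heart-beating donors, 6.55 at 4 h, 6.12 at 16 h and 6.55 at 30 h.

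For each comparison, the 6 arrays can be divided into 3 and 3 in 10 ways, which are too few for a share under 0.05, so chance is neither excluded nor not excluded. At 4 h against heart-beating donors, 3 of 10 splits gave as many genes as the real 1 (highest other 8), 3 as many changed at least 2-fold (real 1, highest other 3) and 2 as many lists (real 12, highest other 13). At 16 h only the real split, 1 of 10, reached 845 genes (highest other 1) and 47 changed at least 2-fold (highest other 1), while 4 reached 11 lists (highest other 14). At 30 h it was 1 of 10 for 3318 genes and for 150 changed at least 2-fold (highest other 0 for both) and 6 for 11 lists (highest other 17). Between 16 h and 4 h it was 1 of 10 for 1511 genes and for 70 (highest other 0) and 3 for 11 lists (highest other 12). Between 30 h and 16 h it was 1 of 10 for 1821 genes and for 115 (highest other 0) and 4 for 14 lists (highest other 17). Between 30 h and 4 h it was 1 of 10 for 3391 genes (highest other 1) and for 146 (highest other 0), and 8 for 9 lists (highest other 14). For all 4 groups 1 of 100 drawn splits, the real one, reached 3785 genes (highest other 1478), so chance can be excluded there.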

How the results depend on the processing

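The Gapdh covariate and the fit without the 30 h arrays were added after the data were seen and applied to the counts alone. Of 495 named gene values, 312 kept their direction and their side of the threshold under every setting planned before, 239 of them past the threshold. With all probe sets one by one, more sequences are tested: 7 changed at 4 h, 1449 at 16 h and 6130 at 30 h against heart-beating donors, 2428 between 16 h and 4 h, 3180 between 30 h and 16 h, 5865 between 30 h and 4 h, and 6602 over all groups. At least 2-fold it was 2, 94, 367, 113, 218 and 371 in the same order. Array weights gave 11 at 4 h (2 at least 2-fold), 2631 at 16 h and 2733 between 16 h and 4 h, and the mean of all probe sets gave 2 at 4 h; the cause was not tested. With only the 2 groups compared, the variance came from those groups alone: 0 genes at 4 h (0 at least 2-fold), 1326 at 16 h, 2210 at 30 h and 974 between 30 h and 16 h. The count rose at 16 h against heart-beating donors and against 4 h (2059), and fell in each comparison with the 30 h arrays. Those arrays had the largest median SD between replicates (0.12), which the main fit shares over all groups. A variance trend with robust settings gave 0 at 4 h (0 at least 2-fold), and so did the replicate block (0 and 0); the cause was not tested. Arrays sharing an animal number showed no pairing, with correlations of deviations from -0.29 to 0.112 in 18 pairs. With the Gapdh 3' minus 5' difference as a covariate, which was higher at 16 h and 30 h and so widens the error there, the counts were 0 at 4 h, 102 at 16 h, 0 at 30 h, 782 between 16 h and 4 h, 7 between 30 h and 16 h, 0 between 30 h and 4 h and 617 over all groups. The main fit had called 57 of the 102 and 362 of the 782. The median change of the genes called before went from 0.45 to 0.20 between 30 h and 16 h, with a median SE of 0.21 after. A slope of the covariate was fitted for each gene and rests on differences within groups. All genes used the same covariate values, and genes are not independent, so errors in the slopes need not average out over genes. The drop therefore cannot tell RNA quality from error. At least 2-fold the counts were 0 at 4 h, 0 at 30 h, 7 between 30 h and 16 h and 0 between 30 h and 4 h. The 2-fold counts at 16 h, against heart-beating donors and against 4 h, stayed nearer to the main fit. Without the 30 h arrays, which varied most, 0 genes changed at 4 h (0 at least 2-fold) and 1526 at 16 h.

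With single arrays left out, the count ranged from 0 to 5 at 4 h, 244 to 1328 at 16 h, 2250 to 3288 at 30 h, 693 to 2034 between 16 h and 4 h, 716 to 2163 between 30 h and 16 h, 2657 to 3360 between 30 h and 4 h and 3028 to 3677 over all groups. At least 2-fold it ranged from 0 to 3, 30 to 74, 92 to 221, 55 to 80, 69 to 141 and 102 to 204 in the same order. The 4 h count was 0 without heart-beating replicate 1 or 3, 4 h replicate 2, any 1 of the 16 h replicates, or 30 h replicate 1 or 2.

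With the mean of all probe sets, Cps1 reversed to -0.81 at 30 h against heart-beating donors, -0.60 against 16 h and -0.83 against 4 h, because its probe sets moved apart, while Hnf4a reversed to -0.08 and Slc25a13 to -0.48 at 30 h against heart-beating donors. After cyclic loess Alb reversed to 0.24 between 30 h and 4 h, and the median of the hepatocyte secreted proteins from -0.08 to 0.15 at 30 h against heart-beating donors and from -0.10 to 0.039 against 16 h; the cause was not tested. At 30 h against heart-beating donors 5 of 28 of these genes were lower and 0 higher (the same counts when adjusted over the list alone). The list was called as lower at the preset correlation (adjusted p = 0.0327; adjusted p = 0.918 with an estimated correlation), and kept this in 14 of 21 settings. Signals near the floor of the arrays cannot fall further and those near the ceiling cannot rise, which limits what dim genes and Alb can show.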

Other observations

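Some groups of genes had no place in the comparisons above. Amino acid catabolism was divided at 30 h against heart-beating donors: 10 of 28 genes were lower and 4 higher (12 and 6 when adjusted over the list alone), with Bhmt, which remethylates homocysteine, at -1.71 (SE 0.19), Tdo2, which opens tryptophan breakdown, at -1.20 (SE 0.16), and Prodh, which starts proline breakdown, at 0.77 (SE 0.09). In lipogenesis 7 of 19 genes were higher and 3 lower (7 and 4 when adjusted over the list alone), with Fasn (0.65, SE 0.14), the fatty acid synthase, higher and Thrsp (-0.75, SE 0.09) lower. In glycolysis 3 of 15 were lower and 0 higher (the same counts when adjusted over the list alone), among them Ldha (-1.26, SE 0.18), which makes lactate. These lists were not called by camera at the preset correlation (adjusted p = 0.0522, 0.848 and 0.108) or with an estimated one (adjusted p = 0.918, 0.99 and 0.918 with an estimated correlation). At the preset correlation the amino acid list stayed uncalled in 15 of 21 settings and was called as lower with a variance trend, with only the groups compared, and without heart-beating donor 3, 16 h animal 1, or 30 h animal 2 or 3.

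Heart-beating donor 2 had the highest signal among the donors in each of 6 immediate early genes, which were chosen after their values were seen and not tested as a list. Its Jun signal was 10.44, against 6.70 and 7.52 in donors 1 and 3, and Egr1 was 8.86 against 6.28 and 6.45. Atf3 was 7.38 against 4.28 and 4.42, and Myc was 8.85 against 5.63 and 5.91. Nr4a1 was 7.25 against 5.38 and 5.17, and Fos was 4.97 against 4.33 and 4.53.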
